A study of Mus musculus with 6 samples.

How the data were processed

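RNA from interscapular brown adipose tissue of C57BL/6 mice was sequenced in 6 samples, 3 from wild-type controls (WT) and 3 from animals that the series title describes as adipocyte-specific Beclin1 knockouts (Beclin1_KO). Per the labels' protocols, RNA was taken up in Trizol and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. Both genotypes received tamoxifen at 75 mg/kg by oral gavage on 5 consecutive days to switch on Cre recombination, per the labels' treatment protocol, although a separate treatment tag of every sample reads untreated. Mice were kept on chow at 22 °C with 12 h of light per day. Groups and replicate numbers were taken from the sample titles, and the series' design text calls the samples biological replicates. Age, sex and the time between tamoxifen and tissue collection were not given in the sources used here.

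The submitters' processing notes name bcl2fastq 2.20.0, Trimmomatic, HISAT2 2.1.0, StringTie 1.3.4d, DESeq2 and the genome build mm10, without roles or order. The gene annotation, the handling of multiply mapped reads and whether counting used the strand were not given in the sources used here. The deposited table held 18507 genes, each with an Entrez Gene number, a symbol and a row total of at least 1 count. Per the file headers, the authors gave read counts per gene, which are whole numbers without normalization. The authors also deposited FPKM values (fragments per kilobase, scaled to sequencing depth), used here only in alternatives. A further block of deposited values is on a log2-like scale whose transformation is not given in the sources used here, and it entered no test. The authors' deposited comparison of both genotypes holds a signed fold change, a score that is negative where the knockout is lower, with a standard error. It also holds the authors' unadjusted p-value and Benjamini-Hochberg adjusted p-value, the latter blank for 726 genes. No gene encoded by the mitochondrial genome was found in the table, so the list of these genes is not analysed here.

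Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 15347 genes and removed 3160. Libraries were scaled by TMM, with factors of 0.83 to 0.94 in WT and 1.09 to 1.19 in Beclin1_KO. A quasi-likelihood model with robust dispersion estimates and the genotype as its only term gave log2 fold changes as Beclin1_KO minus WT. The standard error is the size of the log2 fold change divided by the square root of the F statistic. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and genes with an adjusted p below 0.05 are said to have risen or fallen. The common dispersion was 0.110, a biological coefficient of variation of 33.2%. CPM values are counts per 1e+06 counts of a library, scaled by TMM, and ± gives the SD over n = 3 libraries. Where every WT library was at 0, the fold is a lower bound that takes 3 counts in each WT library as the floor.

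Before the data were examined, 32 gene lists were written down, of which 31 had at least 5 tested members. Genes were matched by symbol alone. Of the symbols not found in the table, 18 were second spellings of a listed gene, and a pair of lists shared up to 6 genes. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with an estimated correlation. The fry test was run beside it. Fry's directional p asks whether a list's genes move one way on balance, and its mixed p whether they change in either direction. List p-values were adjusted over the 31 lists. A further 10 lists were written after the table had been opened and before their own values were computed, and were adjusted among themselves. Genes shared between these added lists and the lists fixed beforehand were not counted.

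The rule for named genes was also fixed beforehand. It took Becn1, the 10 largest rises and 10 largest falls and the 10 smallest adjusted p per direction, among changed genes with an official symbol, groups that did not overlap and a mean of at least 5 CPM. Ties in adjusted p were ordered by unadjusted p. The rule also took up to 4 members per list with the smallest p, and 23 lead genes whether or not they passed. Scd1, Acly, Col3a1, the members of added lists, and members named because 5 or fewer of a list stood apart were chosen after their values were seen. Positions came from the RefSeq annotation of assembly GRCm38.p6, the assembly behind mm10, matched by Entrez Gene number for 18467 of the 18507 genes.

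The alternatives fixed beforehand were RLE and upper-quartile scaling, TMM without the 20 most abundant genes, DESeq2 1.42.0, limma-voom, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with FPKM of at least 1 in 3 samples. Others were no low-count filter, a filter of 1 CPM in all samples of a group, no robust dispersion, the replicate number as a block, leaving out each library, and a 2-fold limit. After the data had been seen, 3 alternatives concerning skeletal muscle were added. One left out the library with the highest muscle genes in each group, another left out the 3 highest libraries, and the last used the mean log2 CPM of the muscle list as a covariate. Figures were drawn with matplotlib 3.10.9.

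The tests were tested on simulated data for 15347 genes with the means and library sizes of this comparison. With edgeR, 0 of 67 genes changed 1.5-fold, 9 of 67 changed 2-fold and 45 of 66 changed 4-fold were recovered, and 6 of 60 calls (10%) were false. DESeq2 recovered 59 of the 66 genes changed 4-fold, and 63 of its 155 calls (40.6%) were false. Far fewer genes changed in the simulation than were called in the data. The share of false calls depends on that number, so these shares do not carry over to the calls reported here or to the authors' deposited table. The simulated list that changed was called, and 0 of 27 lists sharing no gene with it were. Genes were drawn independently in the simulation, while the estimated correlation within the tested lists reached 0.965 in the data. The simulation therefore does not check the list calls reported here. Total counts were 44269031 to 60983193 per library, so that the floor of 3 counts corresponds to 0.0492 to 0.0678 CPM before scaling. Pairs of libraries differed far beyond counting noise, with a chi-square per degree of freedom of 149 or more, so every library was counted as a sample of its own.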

Results

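Gene expression was measured by RNA sequencing in interscapular brown adipose tissue, the heat-producing fat depot between the shoulder blades. The samples were 3 WT mice and 3 Beclin1_KO mice. Beclin 1, the product of Becn1, is a subunit of the lipid kinase complex that starts autophagosome formation. The comparison asks how its loss from adipocytes changes the transcripts of the tissue. Total counts per library were 44269031, 50219212 and 50842488 in WT and 50536315, 53789848 and 60983193 in Beclin1_KO. The most abundant gene of each WT library was Scd1, a fatty acid desaturase, with 2.96% to 3.96% of all counts. In the knockouts the most abundant genes were Acta1, Col3a1 and Fth1, with 0.94%, 0.81% and 0.81%. The correlation of log2 CPM across genes, which are not independent replicates, was 0.954 to 0.975 within WT, 0.942 to 0.969 within Beclin1_KO and 0.849 to 0.896 between the groups.

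Becn1 (Entrez Gene 56208, a protein-coding gene on chromosome 11, 101288258 to 101302286, GRCm38) fell from 86.2 ± 3.20 CPM in WT to 51.5 ± 7.88 CPM in Beclin1_KO. Its log2 fold change was -0.74 (SE 0.13, adjusted p = 0.00411), a 1.67-fold lower level. The values were 82.8, 86.4 and 89.2 CPM in the WT libraries and 58.0, 53.8 and 42.7 CPM in the knockout libraries, without overlap. Groups did not overlap for 59.7% of all genes tested, so this separation does not by itself check the labels. Adipocyte-restricted genes of an added list fell by a median of -1.49 in the same libraries. How much of the fall of Becn1 stems from its deletion was not tested. Whole tissue also holds cells in which an adipocyte Cre does not act, and a gene-level count sums over deleted and retained exons alike. On the FPKM scale, which is not corrected for composition, the log2 fold change was -0.39 with a pseudocount of 1 (adjusted p = 0.0454) and -0.40 with 0.1 (adjusted p = 0.0455).

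Transcripts of fat synthesis, fatty acid oxidation, mitochondria and thermogenesis fell in Beclin1_KO tissue, and transcripts of macrophages, lymphocytes, interferon response, extracellular matrix and lysosomes rose, as lists by camera with a preset correlation, while with an estimated correlation 0 of 31 lists passed. Of 15347 genes tested, 7150 (46.6%) passed, 3810 higher and 3340 lower. Of these, 2667 were at least 2-fold higher and 1441 at least 2-fold lower. The higher genes made up 53.3% of the calls, against 74.2% (4900 higher and 1700 lower) in the fit on log2(FPKM + 1). Over the genes tested in both fits, the median of the per-gene differences in log2 fold change was 0.32, with the FPKM fit higher. Groups did not overlap for 59.7% of the genes tested. Chance gives 10% on average, but genes move together, so a single split can lie far from that average and chance cannot be judged from it. Skeletal muscle transcripts varied widely within both groups. Without the library of each group that was highest in them, 4914 genes passed, 2860 higher and 2054 lower, and without the 3 highest libraries, which leaves 2 WT against 1 knockout, 2915 passed, 1861 higher and 1054 lower. Of the 7150 genes, 4630 and 2711 kept their direction and passed in these fits, and 0 passed in the opposite direction. The fit with 1 knockout library has too few samples to serve as a check on muscle, and where it sets the end of a range it says nothing about stability.

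**Figure D1:**
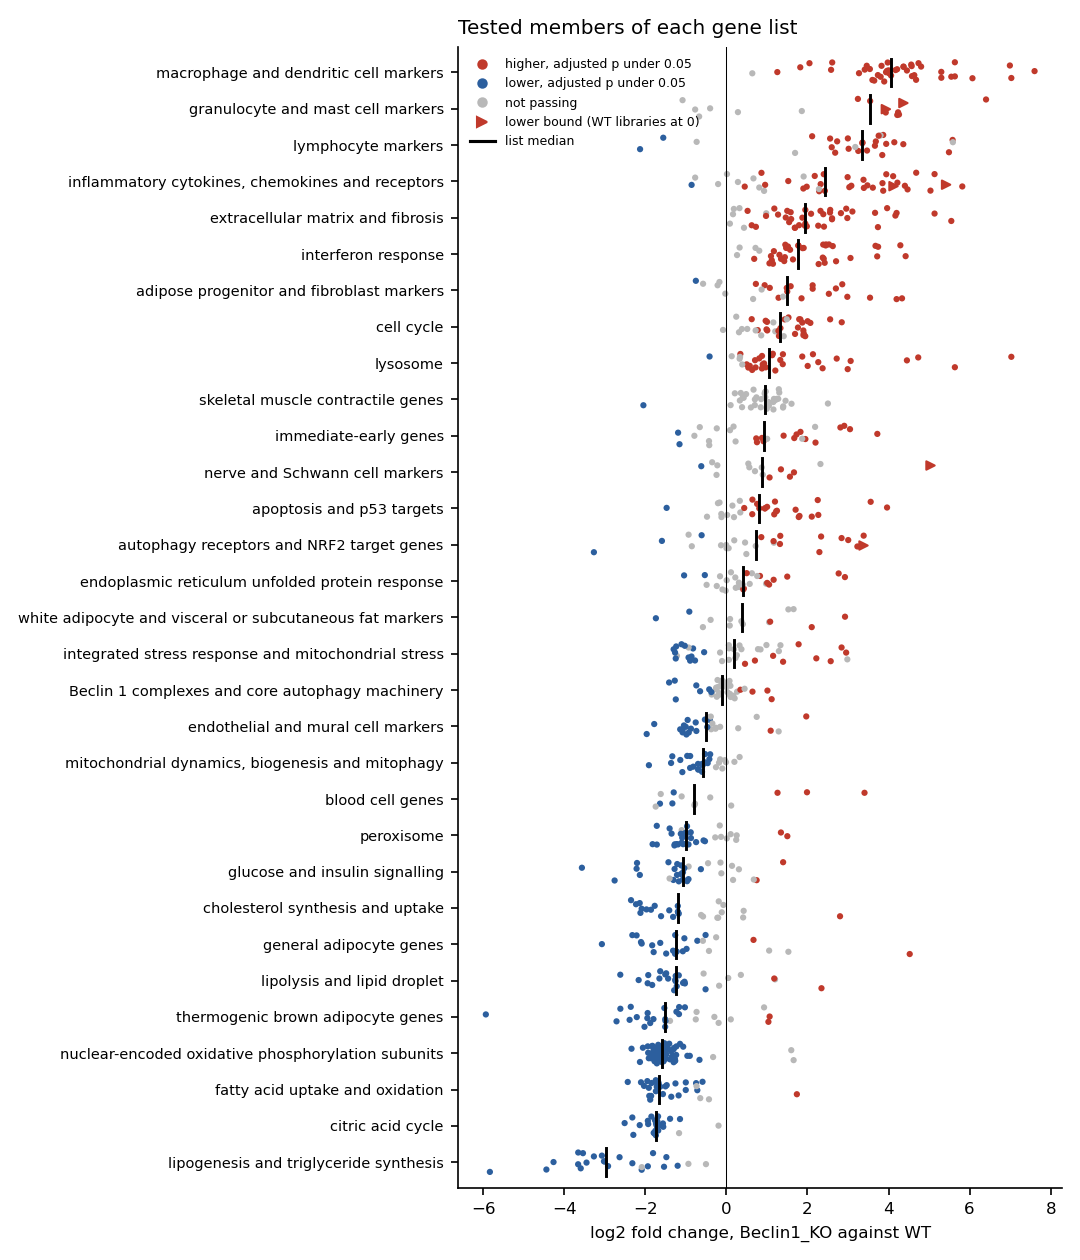
Log2 fold change of every tested member of the 31 gene lists (horizontal axis, Beclin1_KO against WT), with 1 point per gene, colour for genes passing an adjusted p of 0.05, arrowheads for lower bounds where all WT libraries were at 0, and black bars for list medians. Medians ran from -2.96 for lipogenesis to 4.06 for macrophage and dendritic cell markers.

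Among 31 lists, 11 were higher and 12 lower than the remaining genes by camera with a preset correlation. The adjusted p with an estimated correlation stands beside each list.

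Fat synthesis showed the lowest list median. Fatty acid synthase, Fasn, fell 57.1-fold, from 24780 ± 10830 to 434 ± 61.9 CPM (log2 fold change -5.84, SE 0.43, adjusted p = 0.000155). Acaca, the carboxylase that makes malonyl-CoA, fell 19.2-fold from 3801 ± 1847 CPM, and Dgat2, which completes triglycerides, fell 8.41-fold from 2322 ± 437 CPM. Tkt of the pentose phosphate pathway fell 12.6-fold, and Scd1 and Acly fell 12.1-fold and 21.7-fold. Of 24 genes of lipogenesis and triglyceride synthesis, 0 rose, 21 fell and 3 (Dgat1, Elovl5 and Scd2) did not pass, or 23 fell adjusted over the list alone. The median log2 fold change was -2.96 (camera adjusted p = 4.82e-12, adjusted p = 0.274 with an estimated correlation). Without the 3 libraries highest in muscle genes, Acly had a log2 fold change of -4.24, against -4.44 in all libraries, and no longer passed with these fewer samples (adjusted p = 0.097, against 7.71e-18 to 0.097 over 20 alternatives). Without WT replicate 3 the log2 fold change of Acly was -3.78.

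Most genes of the thermogenic list were lower. In the same libraries all 13 genes of an added list of adipocyte-restricted genes fell, with a median of -1.49. No test compared it with the thermogenic list, and shared genes were not counted, so the 2 lists may not be independent. Ucp1, the uncoupling protein of brown fat mitochondria, fell 5.13-fold, from 9750 ± 1798 to 1899 ± 752 CPM (log2 fold change -2.36, SE 0.33, adjusted p = 0.00171). Of 28 thermogenic brown adipocyte genes, 2 rose (Ckb and Zic1), 19 fell and 7 did not pass, with 3 and 20 adjusted over the list alone and a median of -1.51 (adjusted p = 3.94e-07, 0.274 with an estimated correlation). Bmp8b fell 61.2-fold, the proton channel gene Otop1 6.55-fold, the transcriptional regulator Prdm16 4.06-fold and Cidea 3.85-fold. Ppargc1a, a coactivator of mitochondrial gene expression, stood at 104 ± 45.7 and 91.2 ± 47.1 CPM (adjusted p = 0.751). Dio2, the deiodinase that makes active thyroid hormone, had an adjusted p of 0.0466 at a log2 fold change of -1.17. That call of Dio2 was lost without WT replicate 1 (adjusted p = 0.119), WT replicate 3 (0.0966), Beclin1_KO replicate 1 (0.0767) or Beclin1_KO replicate 2 (0.126). It was also lost with the replicate number as a block (0.113), with upper-quartile scaling (0.0507), without a low-count filter (0.0557) and on the FPKM scale (0.123 and 0.126), and Dio2 passed in 10 of 20 alternatives, over a range of 0.00322 to 0.126. Without the library of each group highest in muscle genes, Cidea had a log2 fold change of -1.77, against -1.94, and an adjusted p of 0.0511 (9.4e-07 to 0.0511 over 20 alternatives). Leaving out Beclin1_KO replicate 3 moved Cidea to -2.56, and leaving out Beclin1_KO replicate 2 moved Bmp8b from -5.94 to -6.60.

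Lipid droplet and general adipocyte genes fell by less than fat synthesis in the median. All 13 genes of the added adipocyte-restricted list fell in the same libraries, with a median of -1.49. No test compared that list with the lipid droplet or general adipocyte list. Genes it shares with them were not counted, so it may not be an independent baseline. Of 27 genes of lipolysis and lipid droplets, 2 rose (Faah and Hilpda), 20 fell and 5 did not pass, with the same counts adjusted over the list alone and a median of -1.25 (adjusted p = 1.51e-06, 0.274 with an estimated correlation). The droplet coat protein gene Plin1 fell 3.56-fold, from 1093 ± 71.4 to 307 ± 79.8 CPM. The lipases Lipe and Pnpla2 fell 2.80-fold and 2.40-fold. Prkaca, the catalytic subunit of protein kinase A, fell 3.81-fold. Without Beclin1_KO replicate 2, Pnpla2 had an adjusted p of 0.0551, against 4.8e-05 to 0.102 over 20 alternatives. Without the library of each group highest in muscle genes, Pnpla2 (log2 fold change -1.13, against -1.26, adjusted p = 0.0804) and Pparg (-1.05, against -1.04, adjusted p = 0.0584, with 0.000141 to 0.0834 over 20 alternatives) did not pass. Of 26 general adipocyte genes, 2 rose (Fabp5 and Sncg), 19 fell and 5 did not pass, again with the same counts adjusted over the list alone (median -1.24, adjusted p = 7.9e-06, 0.274 with an estimated correlation). The adipogenic factors Cebpa and Pparg fell 3.10-fold and 2.05-fold, and adiponectin, Adipoq, fell 2.49-fold, while Sncg rose 23.0-fold.

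Most genes fell in the lists of oxidative phosphorylation, the citric acid cycle and mitochondrial dynamics. In the same libraries all 13 genes of an added list of adipocyte-restricted genes fell, with a median of -1.49, and no test compared them with the mitochondrial lists. Of 79 nuclear genes for oxidative phosphorylation subunits, 76 fell, 0 rose and 3 did not pass, with the same counts adjusted over the list alone (median -1.60, adjusted p = 9.11e-30, 0.274 with an estimated correlation). The complex I genes Ndufa1 and Ndufb11 fell 4.39-fold and 3.42-fold, to 106 ± 12.6 and 181 ± 23.3 CPM. The members that did not pass were Atp5g3 (-0.33), Atp5g1 (1.66) and Cox6a2 (1.60), the last being the isoform of striated muscle. Of 25 citric acid cycle genes, 23 fell, 0 rose and Idh2 and Suclg2 did not pass, or 24 fell adjusted over the list alone (median -1.74, adjusted p = 9.37e-13, 0.274 with an estimated correlation). Pdha1 of pyruvate dehydrogenase fell 4.91-fold and Mdh2 3.33-fold. Of 29 genes of mitochondrial dynamics, biogenesis and mitophagy, 21 fell, 0 rose and 8 did not pass, with the same counts adjusted over the list alone (median -0.59, adjusted p = 7.73e-06, 0.274 with an estimated correlation). Mtfp1, a fission factor, fell 3.76-fold and the prohibitin gene Phb2 2.52-fold.

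The lists of this paragraph moved in the same libraries as adipocyte-restricted genes, all 13 of which fell (median -1.49), and macrophage markers, which rose (median 4.06). No test compared these lists. Of 32 genes of fatty acid uptake and oxidation, 28 fell, 3 did not pass (Acot2, Lpl and Pdk4) and Cpt1a rose, with the same counts adjusted over the list alone (median -1.65, adjusted p = 1.9e-11, 0.274 with an estimated correlation). Acsl1, which activates fatty acids, fell 4.31-fold, the carnitine carrier Slc25a20 3.59-fold and the nuclear receptor Ppara 3.87-fold. Cpt1a, the carnitine palmitoyltransferase best known from liver, rose 3.33-fold, from 29.1 ± 4.31 to 96.9 ± 9.17 CPM. Of 34 peroxisome genes, 2 rose (Far1 and Pmp22, the latter a myelin protein), 24 fell and 8 did not pass, with 2 and 25 adjusted over the list alone (in the median 2.00-fold lower, adjusted p = 1.85e-06, 0.274 with an estimated correlation). Of 30 genes of glucose and insulin signalling, 2 rose (Hk1 and Slc2a1), 19 fell and 9 did not pass, with 2 and 20 adjusted over the list alone (median -1.07, adjusted p = 3.9e-05, 0.288 with an estimated correlation). The insulin-responsive glucose transporter Slc2a4 fell 4.65-fold and the kinase Akt2 2.69-fold, while the ubiquitous transporter Slc2a1 rose 2.64-fold. Of 25 genes of cholesterol synthesis and uptake, 15 fell and 9 did not pass, with the same counts adjusted over the list alone (median -1.20, adjusted p = 9.56e-05, 0.395 with an estimated correlation). Hmgcs1, the synthase ahead of HMG-CoA reductase, fell 3.41-fold, and the sterol exporter Abcg1 was the member that rose, 6.98-fold.

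The core autophagy list did not pass as a list moving one way. Fry gave it a directional adjusted p of 0.0627 and a mixed adjusted p of 4.18e-05, the latter for change in either direction. By the mixed p every list but that of skeletal muscle (0.365) passed. Of 37 genes of the Beclin 1 complexes and the core machinery, 4 rose, 7 fell and 26 did not pass, or 3 and 6 adjusted over the list alone (median -0.10, adjusted p = 0.159, 0.531 with an estimated correlation). Vmp1, needed for autophagosome formation at the endoplasmic reticulum, rose 2.02-fold, and Gabarapl1, Pik3r4 and Uvrag also rose. Wipi2, Atg10 and Atg4d, which act in lipidation of ATG8 proteins, fell 2.67-fold, 2.42-fold and 2.38-fold. Map1lc3b stood at 269 ± 4.13 and 322 ± 43.0 CPM (adjusted p = 0.148) and passed on the FPKM scale (0.00867 and 0.00852, against 0.00852 to 0.32 over 20 alternatives). The cargo receptor gene Sqstm1 rose 2.51-fold, from 299 ± 54.7 to 751 ± 131 CPM (log2 fold change 1.33, SE 0.20, adjusted p = 0.00215). Its list of autophagy receptors and NRF2 targets had 11 genes higher, 3 lower (Gsta4, Me1 and Optn) and 11 not passing of 25, with the same counts adjusted over the list alone and an adjusted p of 0.0651 (median 0.72, 0.632 with an estimated correlation). Heme oxygenase, Hmox1, rose 8.03-fold and ferritin light chain, Ftl1, 4.91-fold. In the same libraries macrophage markers rose by a median of 4.06, and no test compared them with the receptor and NRF2 list. This list passed with DESeq2 (adjusted p = 0.024), without WT replicate 3 (0.0431), Beclin1_KO replicate 1 (0.012) or Beclin1_KO replicate 2 (0.0244), with muscle as a covariate (0.0214) and without the library of each group highest in muscle genes (0.0219). The range over 21 alternatives was 0.00019 to 0.173, with the lowest from the fit with 1 knockout library.

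Lysosome genes rose. Of 36, 31 rose, Ctsf fell and Atp6v1h, Mcoln1, Npc1 and Tfeb did not pass, or 33 rose adjusted over the list alone (median 1.05, adjusted p = 4.47e-11, 0.274 with an estimated correlation). The protease gene Ctss rose 49.7-fold to 1081 ± 172 CPM, the macrophage lysosomal protein gene Cd68 21.9-fold, and the hydrolase gene Gla 6.59-fold. The list shares 3 genes with the macrophage list, whose median rose by 4.06 in the same libraries.

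Among the 31 lists fixed beforehand, macrophage and dendritic cell markers showed the highest median. Of 43, 42 rose and Cd163 did not pass, or 43 rose adjusted over the list alone (median 4.06, a 16.7-fold change, adjusted p = 1.25e-28, 0.274 with an estimated correlation). Adgre1, the F4/80 antigen of macrophages, rose 20.7-fold, from 10.6 ± 1.59 to 219 ± 76.5 CPM (log2 fold change 4.37, SE 0.30, adjusted p = 0.00013). The complement gene C1qa rose 14.2-fold and the Fc receptor genes Fcgr3 and Fcer1g 25.6-fold and 16.7-fold. Of 41 genes of inflammatory cytokines, chemokines and receptors, 31 rose, Nos2 fell and 9 did not pass, with the same counts adjusted over the list alone (median 2.43, also with bounds in place of the fits of 2 genes at 0 in WT, adjusted p = 9.37e-13, 0.261 with an estimated correlation). Lipocalin 2, Lcn2, rose 32.8-fold and the chemokine genes Ccl6 and Cxcl16 22.1-fold and 15.4-fold. Ccl2 stood at 7.07 ± 3.76 and 13.5 ± 3.47 CPM (adjusted p = 0.0978) and passed in 6 of 20 alternatives, among them DESeq2 (adjusted p = 0.0431) and the fit without WT replicate 2 (0.0144), over a range of 0.0144 to 0.248.

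Of 39 interferon response genes, 35 rose, 0 fell and 4 did not pass, or 36 rose adjusted over the list alone (median 1.78, adjusted p = 1.77e-14, 0.274 with an estimated correlation). The antiviral genes Mx1, Oas2 and Oas1a rose 19.6-fold, 13.4-fold and 13.2-fold, and the regulator Irf7 6.17-fold. Of 28 lymphocyte markers, 21 rose, 2 fell and 5 did not pass, or 25 and 2 adjusted over the list alone (median 3.36, adjusted p = 3.79e-07, 0.274 with an estimated correlation). The interleukin 7 receptor gene Il7r rose 47.9-fold and the natural killer cell gene Klrb1c 15.4-fold. As a list the lymphocyte markers were low, at 0.00114% to 0.00214% of a library's counts in WT and 0.0181% to 0.0319% in Beclin1_KO. Of 15 granulocyte and mast cell markers, 9 rose, 0 fell and 6 did not pass, with the same counts adjusted over the list alone (median 3.55, also with bounds for 2 genes at 0 in WT, adjusted p = 0.000434, 0.274 with an estimated correlation). The mast cell protease genes Cma1, Tpsb2 and Cpa3 rose 18.6-fold, 18.8-fold and 15.3-fold. The granulocyte and mast cell list was also low, at 0.00127% to 0.00337% of counts in WT and 0.01261% to 0.01975% in Beclin1_KO.

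Matrix genes rose as well. Col1a1, a chain of type I collagen, rose 5.24-fold, from 491 ± 113 to 2573 ± 629 CPM (log2 fold change 2.39, SE 0.27, adjusted p = 0.000734). Col3a1 rose 5.00-fold to 5814 ± 1475 CPM. Of 45 genes of extracellular matrix and fibrosis, 39 rose, 0 fell and 6 did not pass, with the same counts adjusted over the list alone (median 1.95, adjusted p = 2.96e-14, 0.274 with an estimated correlation). The macrophage metalloelastase gene Mmp12 rose 46.8-fold, the protease inhibitor gene Timp1 35.1-fold, and the proteoglycan gene Bgn 6.08-fold. Of 25 adipose progenitor and fibroblast markers, 17 rose, Zfp423 fell and 7 did not pass, or 18 rose adjusted over the list alone (median 1.49, adjusted p = 6.76e-06, 0.274 with an estimated correlation). Pdgfra, the platelet-derived growth factor receptor of progenitors, rose 6.50-fold, and Fgf10 rose 20.1-fold. Of 28 endothelial and mural cell markers, 2 rose (Plvap and Vwf), 16 fell and 10 did not pass, or 2 and 17 adjusted over the list alone (median -0.50, adjusted p = 0.000402, 0.370 with an estimated correlation). The VEGF receptor gene Kdr fell 3.44-fold and the pericyte gene Cspg4 3.91-fold, while Plvap, of fenestrated endothelium, rose 3.92-fold.

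**Figure D2:**
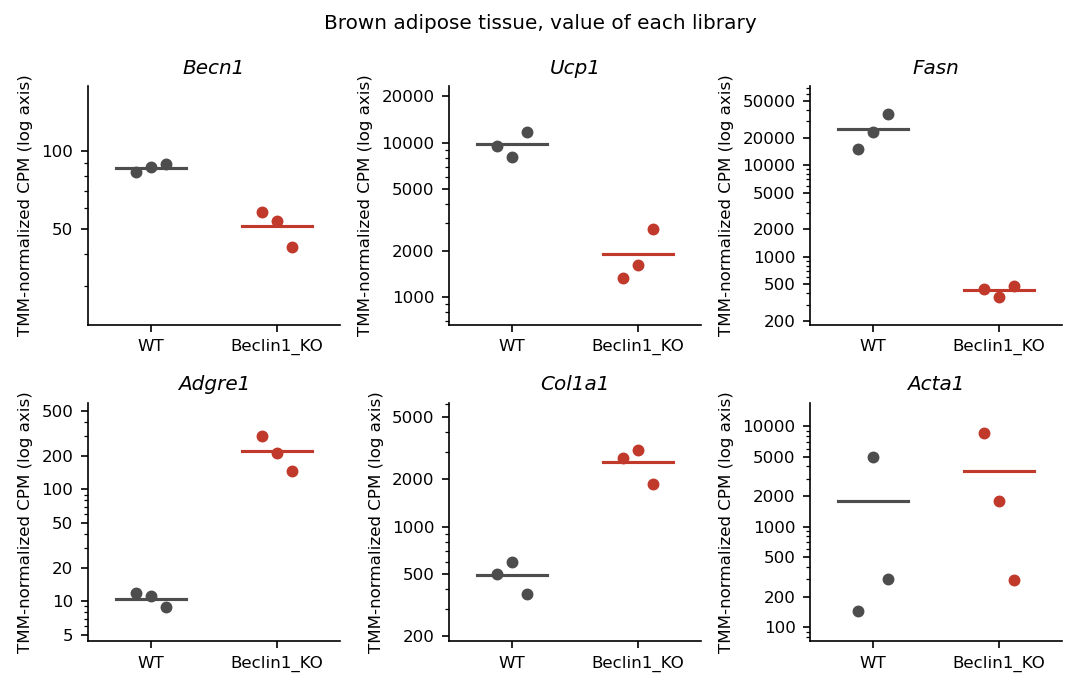
TMM-normalized CPM (vertical axes, log scale) of 6 genes in each library, with 1 point per library and a line at the group mean. Becn1, Ucp1 and Fasn lay lower and Adgre1 and Col1a1 higher in all 3 Beclin1_KO libraries than in any WT library, and Acta1 overlapped, with means of 1795 and 3581 CPM.

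Stress lists gave mixed results. Of 39 genes of the integrated stress response and mitochondrial stress, 9 rose, 12 fell and 18 did not pass, or 10 and 12 adjusted over the list alone. The median was 0.19 and the mean 0.29, while camera placed the list lower (adjusted p = 0.689, 0.919 with an estimated correlation). The glutathione-degrading enzyme gene Chac1 and the serine synthesis gene Psat1 rose 5.95-fold and 3.44-fold, and the translation repressor gene Eif4ebp1 fell 2.36-fold. Atf4, the central factor of the response, stood at 214 ± 59.3 and 198 ± 68.0 CPM (adjusted p = 0.785), and Ddit3 at 32.9 ± 1.42 and 39.3 ± 1.31 CPM (adjusted p = 0.0523). Ddit3 passed in 5 of 20 alternatives, which were DESeq2 (adjusted p = 0.0489), the 1 CPM filter (0.043), no robust dispersion (0.0481) and both FPKM fits (0.00389 and 0.00386), over a range of 0.00386 to 0.269. The stress hormone genes Fgf21 (0.200 ± 0.194 and 1.58 ± 1.96 CPM, adjusted p = 0.147) and Gdf15 (4.18 ± 2.31 and 10.5 ± 7.28 CPM, adjusted p = 0.154) did not pass. In the muscle alternatives, Fgf21 passed with the covariate (0.0388, against 0.0258 to 0.5 over 17 alternatives, the lowest from the fit with 1 knockout library), and Gdf15 without 2 libraries (0.0429, against 0.0429 to 0.427 over 20). Of 29 genes of the endoplasmic reticulum unfolded protein response, 10 rose, 2 fell (Derl1 and Dnajb2) and 17 did not pass, with the same counts adjusted over the list alone (median 0.41, adjusted p = 0.114, 0.616 with an estimated correlation). Sdf2l1 rose 7.59-fold and the transcription factor gene Xbp1 2.01-fold, while the chaperone gene Hspa5 stood at 419 ± 34.9 and 624 ± 227 CPM (adjusted p = 0.126). Without Beclin1_KO replicate 3, this list passed at 0.0227 (0.0227 to 0.367 over 21 alternatives) and Hspa5 at 0.0111 (0.0111 to 0.745 over 20). The list also passed by fry (0.0385), and Hspa5 on the FPKM scale (0.0354 and 0.0349).

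The lists of this paragraph moved in the same libraries as macrophage and lymphocyte markers, whose medians rose by 4.06 and 3.36. Of 31 genes of apoptosis and p53 targets, 20 rose, Phlda3 fell and 10 did not pass, with the same counts adjusted over the list alone (median 0.81, adjusted p = 0.000214, 0.274 with an estimated correlation). The proapoptotic genes Pmaip1, Bid and Bax rose 15.6-fold, 4.77-fold and 2.01-fold, and the initiator caspase gene Casp8 2.34-fold. Pmaip1 was low in WT, with 8, 16 and 12 counts. Of 27 immediate-early genes, 14 rose, 2 fell (Klf2 and Klf4) and 11 did not pass, or 16 and 3 adjusted over the list alone (median 0.92, adjusted p = 0.00916, 0.288 with an estimated correlation). Atf3 rose 7.50-fold, Egr2 8.28-fold and Fos 3.55-fold. The call of this list was lost on the FPKM scale (adjusted p = 0.0992 and 0.0984, against 0.000672 to 0.0992 over 21 alternatives). Of 35 cell cycle genes, 24 rose, 0 fell and 11 did not pass, or 26 rose adjusted over the list alone (median 1.33, adjusted p = 1.53e-05, 0.442 with an estimated correlation). The replication licensing genes Mcm6 and Mcm3 rose 2.43-fold and 2.01-fold, and the proliferation marker Mki67 3.75-fold, from 4.59 ± 0.971 to 17.2 ± 10.4 CPM. Mki67 no longer passed without WT replicate 1 (adjusted p = 0.0594) or WT replicate 2 (0.0582) or in limma-voom (0.0556), over a range of 6.3e-05 to 0.0594 in 18 alternatives.

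Skeletal muscle genes differed more within the groups than between them. The mean log2 CPM of the 37 muscle genes was 3.70, 8.89 and 5.07 in the WT libraries and 9.58, 7.19 and 4.63 in the knockout libraries, and they took 0.369% to 6.45% of a library's counts. Acta1, skeletal muscle actin, had 5988, 221260 and 12680 counts in WT and 476582, 115492 and 19800 in Beclin1_KO (adjusted p = 0.676). Of the 37, 0 rose, 36 did not pass and Car3, a carbonic anhydrase also abundant in fat, fell 4.13-fold, with the same counts adjusted over the list alone (median 0.96, adjusted p = 0.603, 0.919 with an estimated correlation). Without WT replicate 2 this list passed as higher (adjusted p = 0.00822, against 0.00822 to 0.893 over 21 alternatives), and so it did without the library of each group highest in it (median 2.11, adjusted p = 0.02). Without Beclin1_KO replicate 1 its median was -0.69.

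Of 14 white fat markers, 3 rose (Npr3, Nrip1 and Trim14), 2 fell (Hoxc8 and Rb1) and 9 did not pass, with the same counts adjusted over the list alone (median 0.39, adjusted p = 0.603, 0.632 with an estimated correlation), while fry called the list higher (adjusted p = 0.017, against 0.017 to 0.961 over 21 alternatives). Npr3, a natriuretic peptide receptor, rose 4.30-fold. Of 13 blood cell genes, the platelet genes Gp1bb, Itga2b and Pf4 rose, the erythroid genes Alas2, Hba-a2 and Hbb-b2 fell and 7 did not pass, with the same counts adjusted over the list alone (median -0.79, adjusted p = 0.298, 0.631 with an estimated correlation). Pf4 rose 3.97-fold, and Hba-a1, which can share reads with its near-identical copy Hba-a2, had means of 11.6 and 6.79 CPM (adjusted p = 0.172) and passed with muscle as a covariate (0.0414, against 0.0414 to 0.429 over 20 alternatives). Of 15 nerve and Schwann cell markers, 5 rose (Cnp, Mag, Npy, Pmp22 and Uchl1), Mbp fell and 9 did not pass, with the same counts adjusted over the list alone (median 0.87, adjusted p = 0.0651, 0.370 with an estimated correlation). The nerve list passed with the replicate number as a block (adjusted p = 0.0444) and by fry (0.00484), over a range of 0.00484 to 0.328 in 21 alternatives. Npy, neuropeptide Y, had 0 counts in WT and 2.27 ± 0.722 CPM in Beclin1_KO, at least 32.4-fold higher.

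By size, the genes that rose most were Cd1d2, Hpca, Spp1, Frem1, Atp6v0d2, Gpnmb, Stac2, Ubd, Alx4 and Trem2. WT counts were near the floor for Hpca (5, 0 and 0), Frem1 (8, 11 and 0), Stac2 (7, 9 and 9) and Alx4 (5, 6 and 4), so their ranks are uncertain. The log2 fold change of Hpca moved from 7.99 to 12.17 without WT replicate 1 and to 7.40 without WT replicate 2. That of Frem1 moved from 7.35 to 7.95 without WT replicate 2 and to 6.77 without WT replicate 3. Osteopontin, Spp1, rose 194-fold from 1.54 ± 0.457 to 300.5 ± 184 CPM, Gpnmb 127-fold from 7.99 ± 2.76 to 1018 ± 555 CPM, the vacuolar ATPase subunit gene Atp6v0d2 131-fold and the lipid receptor gene Trem2 67.2-fold. Without Beclin1_KO replicate 1 the log2 fold change of Spp1 moved from 7.60 to 6.99. Cd1d2, annotated as a transcribed pseudogene, had 0 counts in all 3 WT libraries and 10.3 ± 4.21 CPM in Beclin1_KO, at least 147-fold higher, and its close relative Cd1d1 makes the assignment of its reads uncertain. The largest falls were those of Slc2a5, Bmp8b, Fasn, H2-Q10, Sorcs2, Cyp2b10, Ttc25, Sugct, Ntrk3 and Cyp1a1. The fructose transporter gene Slc2a5 fell from 51.0 ± 42.7 to 0.0834 ± 0.0576 CPM. Its WT libraries ranged from 10.2 to 95.4 CPM and its knockout libraries held 8, 2 and 5 counts, close to the floor of 3, so the fold of 611 is uncertain. Its log2 fold change of -9.26 moved to -8.46 without WT replicate 3 and to -9.85 without Beclin1_KO replicate 1. H2-Q10, one of a family of similar class I genes, fell 36.0-fold. The neurotrophin receptor gene Ntrk3 fell 23.3-fold from 328 ± 23.8 CPM. Slc2a5 did not pass in limma-voom (adjusted p = 0.135, against 7.6e-18 to 0.135 over 20 alternatives). Cyp2b10 did not pass without Beclin1_KO replicate 2 (0.072) or in limma-voom (0.0611, against 3.97e-05 to 0.072 over 20 alternatives). Ttc25 did not pass without Beclin1_KO replicate 3 (0.0504), with the replicate number as a block (0.0658) or in limma-voom (0.0635, against 3.31e-06 to 0.123 over 20 alternatives). Ttc25 lies beside Cnp, and whether counting used the strand was not given in the sources used here. Ttc25 (100545608 to 100572566) also lies on chromosome 11 near Becn1 (101288258 to 101302286), and whether this bears on its fall was not tested.

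By adjusted p, with ties ordered by unadjusted p, the leading rises were Ms4a6d, Emp1, Ifi204, Fcgr2b, C1qa, Fcer1g, Egfr, Uap1l1, Fcgr3 and Csf2rb2. Each had an adjusted p of 2.3e-05, which genes with a larger unadjusted p can share. Ms4a6d rose 32.2-fold, Emp1 20.4-fold, from 14.1 ± 1.21 to 288 ± 5.26 CPM, and the epidermal growth factor receptor gene Egfr 11.7-fold. The leading falls were H2-Q10, Rnf152, Hsd11b1, Gypc, Pcdh12, Ube2v1, Cxadr, Inafm2, Acbd4 and Cntnap1. Of these, Cntnap1 (chromosome 11, 101174617 to 101190724) lies close to the targeted gene Becn1 (101288258 to 101302286). Acbd4 (103101688 to 103112199) lies farther off on the same chromosome. Whether nearness to the targeted gene bears on their falls was not tested. Hsd11b1, which regenerates active glucocorticoid, fell 11.6-fold from 195 ± 28.2 to 16.7 ± 2.39 CPM. The junction protein gene Cxadr fell 11.9-fold, and Rnf152 6.65-fold. Members of gene families with close copies, among them Fcgr2b, Fcgr3, Csf2rb2, Ifi204, Oas1a and Tpsb2, can share reads with relatives, and their values are uncertain to that extent.

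In the authors' deposited table, 7871 genes had an adjusted p below 0.05, 4288 higher and 3583 lower in the knockout. Of the 7150 genes called here, 7136 were also called in the authors' deposited table in the same direction and 0 in the opposite one. With an unadjusted p below 0.05 and a 2-fold limit, the authors' deposited table held 4749 genes, of which 4109 were called here in the same direction. For Becn1 the authors' deposited table gave a signed fold change of -1.67 and an adjusted p of 1.8e-05. A DESeq2 fit of the deposited counts gave log2 fold changes within 0.001 of the authors' deposited table for 18506 of 18507 genes.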

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

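The skeletal muscle alternatives were chosen after seeing the data. Becn1 stayed lower and past the threshold in all 20 alternatives run on it, and 0 of the 7150 genes passed in the opposite direction in any alternative. The 23 list calls held in every refit of the genes except that of immediate-early genes on the FPKM scale, and fry called them too, but camera with an estimated correlation called 0 of the 23. Leaving out 1 library gave 5548 to 7229 genes, 2983 to 3790 higher and 2492 to 3439 lower, and a Becn1 log2 fold change of -0.84 to -0.63. Deviations of same-numbered libraries from their group means correlated at -0.309, 0.0698 and 0.276. With 3 libraries per group these values cannot decide whether the replicate numbers pair the samples. The fit with the replicate number as a block called 6403 genes, and not every library correlated best with its own number. Chance cannot be judged from other splits, since 10 splits of 3 against 3 are too few for a share under 0.05.

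Counts that moved by over 1.5 times were these. With a 2-fold limit 4108 genes remained in place of 7150, by construction, and with the authors' unadjusted p and 2-fold limit 4109 were shared in place of 7136. The fit on log2(FPKM + 1) gave 1700 lower genes, 590 of them at least 2-fold, and that on log2(FPKM + 0.1) gave 1699 and 716. FPKM is not scaled for composition, and the cause was not tested further. Without the library highest in muscle genes of each group, 2054 genes were lower. Without the 3 highest libraries 2915 passed, 1861 higher and 1054 lower, and 1692 and 819 were at least 2-fold higher and lower, with fewer samples. Estimating the correlation within lists left 0 lists, 0 higher and 0 lower, where fry called 26 lists, 14 higher and 12 lower, adding the unfolded protein response, white fat and nerve lists to the 23.

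Among the named genes, the calls of Cidea, Pnpla2, Pparg, Bhlhe41 and Dcstamp were lost without the library of each group highest in muscle genes, at log2 fold changes of -1.77, -1.13, -1.05, 0.62 and 4.13. Without the 3 highest libraries, Acly, Adipoq, Alas2, Cnp, Derl1, Fos, Hba-a2, Itga2b, Mag, Mrpl12, Nrg4, Psmb3, Psmb7, Rb1, Slc2a5, Tef and Ttc25 were among those lost, with only 1 knockout library left.

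Directions that turned belonged to genes and lists that had not passed, and the cause was not tested. On log2(FPKM + 1) and log2(FPKM + 0.1), Ppargc1a was at 0.12 and 0.13 and Atf4 at 0.23 and 0.23. The list tests turned to higher for core autophagy (medians 0.27 and 0.28) and to lower for muscle (medians 1.46 and 1.73). The muscle list also turned to lower with DESeq2 (median 0.96) and with muscle as a covariate (0.20), where Ppargc1a was at 0.0336. Without the 3 libraries highest in muscle genes, Ppargc1a was at 0.28, Atf4 at 0.32 and Hspa5 at -0.10, the stress response list turned to higher (0.32) and the white fat list to lower (0.15). Fry placed the stress response list higher (0.19). Leaving out 1 library gave ranges of -0.70 to 0.19 for Ppargc1a, -0.43 to 0.10 for Atf4, -0.49 to 5.11 for Sln, -0.12 to 3.98 for Myoz1, -0.78 to 3.99 for Acta1, -0.69 to 3.95 for the muscle list and -9.9e-05 to 0.27 for the stress response list. The added list of secreted factors turned to higher in leave-one-out fits (-0.0635 to 0.88), without 2 or 3 muscle-rich libraries (0.92 and 1.11), with the covariate (0.0903) and by fry (-0.0782). No alternative varied the depth of 44269031 to 60983193 counts per library, so what it limits was not tested. In the simulation, where far fewer genes changed than here and the adjusted threshold is therefore stricter, 1.5-fold changes were recovered for 0 of 67 genes by edgeR and 6 of 67 by DESeq2.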

Other observations

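Several gene groups were described only after the table had been opened, with lists written before their own values were computed. Complement genes rose, 14 of 17, with 0 lower (median 3.24, or 3.05 with the gene at 0 in WT at its bound, adjusted p = 2.79e-11, 0.0561 with an estimated correlation), among them C1qb 18.0-fold, C3ar1 33.1-fold and C4b 11.1-fold. C1qb is also in the macrophage list, whose median rose by 4.06 in the same libraries. No test compared that list with the complement or osteoclast genes. Of 10 genes of cell fusion and osteoclasts, 6 rose and 0 fell (median 2.97, adjusted p = 0.00586, 0.312 with an estimated correlation), with the protease gene Ctsk up 26.6-fold and the fusion receptor gene Dcstamp up 18.8-fold, a log2 fold change of 4.23 that was 5.00 without WT replicate 1 and 3.64 without WT replicate 3. The lists that fell in this paragraph did so in the same libraries in which all 13 adipocyte-restricted genes fell (median -1.49), and no test compared them. Genes that break down branched-chain amino acids fell, 18 of 19, with 0 higher (median -1.35, adjusted p = 8.3e-10, 0.259 with an estimated correlation). The mitochondrial carrier gene Slc25a44 fell 3.06-fold, Bckdha 3.20-fold and Pccb 4.06-fold. Mitochondrial ribosome genes fell in 51 of 52 cases (median -0.90, adjusted p = 4.98e-17, 0.256 with an estimated correlation), among them Mrpl34 3.60-fold and Mrpl12 2.16-fold, and 21 of 31 proteasome genes fell (median -0.46, adjusted p = 2.91e-05, 0.312 with an estimated correlation), among them Psmb3 2.00-fold and Psmb7 1.84-fold.

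Of 15 genes for factors secreted by brown fat, 5 rose, 5 fell and 5 did not pass (median -0.08, mean 0.28, adjusted p = 0.892, 0.897 with an estimated correlation). Metrnl and Slit2 rose 6.57-fold and 21.2-fold, and Angptl8 and Nrg4 fell 8.09-fold and 3.56-fold. Of 17 circadian clock genes, 1 rose (Bhlhe41), 3 fell, among them Hlf and Tef, and 13 did not pass (median -0.29, adjusted p = 0.12, 0.393 with an estimated correlation), or 0 and 1 adjusted over the list alone. The clock list passed without Beclin1_KO replicate 1 (adjusted p = 0.0365) and without the library of each group highest in muscle genes (0.0189, against 0.0189 to 0.211 over 21 alternatives), and the single-gene calls of Bhlhe41 and Tef were each lost without at least 1 library, with adjusted p up to 0.136 and 0.113, over ranges of 0.00625 to 0.427 and 0.00856 to 0.113, and passed in 11 and 12 of 20 alternatives.

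Among the tests that follow, those of muscle carried along, of the adipocyte share and of scaling were chosen after their results were in part seen, and that of muscle as a covariate after the muscle signal had been seen. The first pattern is the large number of calls and the muscle signal within both groups. The real split of the 6 libraries gave 7150 genes and the highest of the other 9 gave 1, and 1 of 10 splits gave as many, which is too few splits for a share under 0.05. Differing amounts of skeletal muscle argue poorly for these calls as a whole, since 93% kept their direction and passed with muscle content as a covariate. Muscle carried along with the fat pad may account for the spread of the muscle genes themselves, whose pairs had a median correlation of 0.986 over the libraries, against -5.87e-06 for random genes. Dissection and a true difference between animals stay open.

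The second pattern is that fat-synthesis genes fell more than adipocyte-restricted genes, of which all 13 fell (median -1.49, adjusted p = 3.96e-07, 0.207 with an estimated correlation). A lower share of adipocyte RNA alone would lower both alike, but the list medians differed by -1.48 (24 against 13 genes, permutation of list labels, two-sided p = 0.00169). The permutation treats genes as independent, while the estimated correlations within the fat-synthesis and adipocyte-restricted lists were 0.609 and 0.395. Its p therefore does not measure the spread between animals. A scaling factor shifts both lists alike, so the difference of -1.5 to -1.47 over 5 scalings was fixed beforehand and says nothing about scaling. A change of fat-synthesis transcripts within the remaining adipocytes is a candidate explanation, and a loss of the adipocytes richest in them stays open, as bulk tissue does not separate cells.

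The third pattern is that markers of other cell types moved apart. A lower share of adipocyte RNA alone would raise them alike, but the macrophage and the endothelial and mural medians differed by 4.56 (two-sided permutation p = 1e-05, the smallest that the permutations can give). Genes of lipid-associated macrophages rose, 12 of 14, with 0 lower (median 4.69, adjusted p = 1.37e-09, 0.207 with an estimated correlation), and those of resident macrophages rose, 9 of 12, with 0 lower (median 1.83, adjusted p = 1.16e-05, 0.0841 with an estimated correlation), with Clec7a up 49.7-fold and Folr2 up 4.90-fold. More macrophages of the kind present in WT alone would raise both alike, but the medians differed by 2.85 (two-sided permutation p = 0.0164). The fixed macrophage and dendritic cell list had a median of 4.06, so it was the resident list that lay lower. The permutation treats genes as independent, while the estimated correlations were 0.448 in the lipid-associated and 0.0399 in the resident list. Its p therefore cannot exclude that explanation. Where macrophages behind these transcripts came from stays open, since bulk counts measure neither recruitment nor lipid uptake. Genes in a list are not independent samples, so the permutation p-values do not measure the spread between animals.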
